A study of Acomys cahirinus and Mus musculus with 6 samples.

How the data were processed

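Ear punch wounds of spiny mice and laboratory mice were profiled by droplet single-cell RNA sequencing. Per the labels' protocols, tissue was dissociated with a bacterial protease and a Dounce homogenizer, red cells were lysed, and libraries were made with 10x Genomics Chromium reagents that carry unique molecular identifiers (UMIs). Cell Ranger 6.1.1 is named in the submitters' processing notes together with the mouse build GRCm38, also called mm10. Whether this reference was used for the spiny mouse reads, and the filters on cells, are not given in the sources used here. The authors' table holds whole-number UMI counts per gene and cell, as deposited, for 20381 genes in 39577 cells. A second deposited table gives for each cell its library, a cluster number, a cell type name, its total UMI count, its number of genes, and the percent of its UMIs from mitochondrial, ribosomal and haemoglobin genes, per the file headers. The smallest number of genes in a cell was 501 in every library. All 6 libraries carry mouse gene symbols, 5345 of the genes had 0 UMIs in every spiny mouse cell and 986 in every mouse cell, and 12 of 13 mitochondrial genes had 0 UMIs in the spiny mouse. A spiny mouse value is thus what was counted under a mouse name, genes that diverged may be undercounted, and no ratio across species was computed.

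Each group was 1 library, so no test, p-value or standard error was computed. The comparisons were each inhibitor against DMSO in the spiny mouse and FGF2 and NRG1 against PBS in the mouse. UMI counts were summed per library and cell class and scaled to the UMIs of that class. The log2 ratio of CPM was taken with a pseudocount of 1 UMI added to each count. Where depths differ, this makes genes of few UMIs look higher in the library with fewer UMIs in that class. The 95% interval of a ratio is the exact conditional binomial (Poisson) one, which covers counting error only. A gene with 0 UMIs on one side was given a bound computed from a floor of 3 UMIs. This bound, printed as at least a given fold, leaves out the counting error of the other side. The exact interval can therefore reach a smaller fold, most of all where the other side has few UMIs. Shares of cells have exact Clopper-Pearson 95% intervals, which also cover counting error only. Depth per library is given with the results, and the smaller the class, the wider these intervals.

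Before the data were examined, 24 programme lists and 18 cell type marker lists were fixed, with the rule for named genes, the comparisons and the first set of alternatives. A list member was used with at least 30 UMIs over both libraries, and members at or beyond 1.5-fold were counted in each direction. For a list, the median, its interval over members from binomial order statistics, and its percentile among 10000 random lists matched in 20 bins of expression were computed. No interval is given for a list of 5 or fewer members, since even their full range covers less than 95%. Genes were named by rule among those with at least 50 UMIs over both libraries and 50 CPM in the higher one, leaving out mitochondrial, ribosomal, haemoglobin and sex-linked genes and gene models. The 8 highest and 8 lowest ratios were taken in fibroblasts, and the 5 and 5 in keratinocytes and cluster 6 where both libraries held at least 100 cells. To these were added up to 4 members of each list and Dusp6, Spry2, Spry4, Etv4, Etv5, Col1a1, Col3a1, Acta2, Postn and Tnc. A few further list members, Lum and Bgn among them, and the genes named in endothelium and chondrocytes were chosen after their values were seen. Some genes that the rule names are not reported here. Coordinates come from GENCODE vM21 on GRCm38.

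Cell types are the authors' annotation. For each cluster the 10 leading genes by fold were compared with the marker lists, and a cluster that led with more markers of another type was kept out of its class, a decision made after seeing the data. Fibroblasts are therefore cluster 32 alone. Cluster 34, annotated as fibroblasts, led with Schwann cell markers, and cluster 45, annotated as resident macrophages, with mast cell genes. Cluster 6, annotated as resident macrophages, led with 3 dendritic cell markers and 2 macrophage markers, and cluster 7, annotated as circulating monocytes, with 5 neutrophil markers, so both are given by number. Epidermal keratinocytes are the interfollicular clusters without 5 that failed this check, and the share of cells so left out is given with the shares. Lists were read in a class with at least 30 cells in both libraries; the ERK inhibitor fibroblasts, with 5 cells, are the exception, since fibroblasts were fixed as a class to report. A gene was put at the level of free RNA, that is RNA released by other cells into the droplets, when it was under 3 times the lowest other class of the same library and over 10-fold below the type with most, among types of at least 15 cells.

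Correlations across genes used at least 100 UMIs over each pair of libraries. Those between inhibitors were set beside unchanged libraries simulated in 100 Poisson draws from the pooled profile against the same control, and beside the overlap of independent lists. Doublets were scored per library with Scrublet as built into scanpy 1.11.5, but its automatic threshold marked 7 of the 39577 cells, where a rate of 0.8% per 1000 cells would give 0.505% to 12.3% per library. It therefore did not work here, and no cell was removed in the values reported. Counting used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, figures matplotlib 3.10.9, and TMM factors came from edgeR 4.0.16 in R 4.3.3.

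The ratios were tested on simulated data, with counts drawn from the pooled profile at the real library sizes and 200 genes changed. In the ERK inhibitor comparison 95% of genes changed 2-fold and 100% of those changed 4-fold passed 1.5-fold in the right direction in keratinocytes (10128 genes), and 66% and 96% in fibroblasts (3188 genes), where 31.1% of unchanged genes also passed. For the ErbB2 inhibitor 98% of 2-fold changes were recovered in keratinocytes (10760 genes) and 94% in fibroblasts (4771 genes), for the FGFR inhibitor 96% (10518 genes) and 88% (3685 genes), and for FGF2 and NRG1 97% (11084 genes) and 84% (5611 genes), with 4.18%, 8.32% and 18.3% of unchanged genes past 1.5-fold in these fibroblasts. Single genes past 1.5-fold in the small fibroblast classes are read with their intervals for that reason. Counts were simulated with counting error only, without differences between cells, so the real rates can be worse in classes of few cells. The intervals leave out such differences too. In ERK inhibitor fibroblasts, for example, Tnc changed direction without the deepest cell of each library (−3.91).

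Alternatives were TMM scaling, totals without mitochondrial, ribosomal and haemoglobin genes, a mean over cells, list minimums of 10 and 100 UMIs, a pseudocount of 5 UMIs, cells with at least 500 genes and under 10% mitochondrial UMIs, cells without Scrublet's calls, cells thinned to 1000 UMIs and cells whose own class's markers outnumber those of each other type. Others were 10 expression bins, a minimum of 300 UMIs for correlations, correlations without ribosomal, mitochondrial and dissociation genes, and shares without immune cells. Thinning left out 51, 12, 80 and 13 shallower keratinocytes of the DMSO, ERK, ErbB2 and FGFR inhibitor libraries, 36 with PBS and 55 with FGF2 and NRG1. TMM shifted every gene by 0.36 in cluster 7 with the ERK inhibitor, by −0.13 in ERK inhibitor endothelium, by −0.11 in cluster 7 with FGF2 and NRG1 and by 0.11 in ErbB2 inhibitor keratinocytes. Added after seeing the data were the removal of the cells with the highest doublet scores at the expected rate, the whole annotated type, removal of the deepest cell of each class in each library, removal of genes at the free RNA level, keratinocyte clusters weighted as in the control library, and ratios without a pseudocount, with all UMIs and with thinned cells. By a rule also set after seeing the data, an alternative gave no value where the pseudocount alone set the sign of its ratio or median, or where that was infinite without one.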

Results

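Single-cell RNA profiles were collected from healing ear punch wounds of 2 rodents. The spiny mouse (Acomys cahirinus) is known for regrowing ear tissue after such a punch, whereas in the laboratory mouse the wound margin heals with scar. Of the 6 libraries, 4 came from spiny mice given the vehicle DMSO, an ERK inhibitor, an ErbB2 inhibitor or an FGFR inhibitor from day 12 to day 15. The other two came from laboratory mice in which beads soaked in PBS or in the growth factors FGF2 and NRG1 were implanted on day 10. ERK is the last kinase of a signalling cascade that FGF and ErbB receptors start. Each group was 1 library, so there were no replicates and no test was run. Intervals cover counting error only, and a difference here compares libraries rather than conditions. The table held 20381 genes in 39577 cells. The DMSO library had 15363 cells and 70058081 UMIs, with a median of 3125 UMIs per cell, and the ERK inhibitor library had 631 cells and 7429819 UMIs, with a median of 6915. There were 10632 cells and 62542847 UMIs with the ErbB2 inhibitor (median 4153), and 4782 cells and 33564162 UMIs with the FGFR inhibitor (median 5162.5). PBS beads gave 3065 cells and 22572569 UMIs (median 3852), and FGF2 and NRG1 beads gave 5104 cells and 30624949 UMIs (median 3904). Spiny mouse reads were counted under mouse gene names, so ratios were taken only within a species.

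Ratios are log2 of treated over control CPM within the cell class, with 95% intervals in brackets, and a list member is called higher or lower from 1.5-fold. For a list, the interval of its median is taken over members, and its percentile is the place of that median among 10000 random lists matched on expression. The genes followed in each comparison lie, in build GRCm38 with GENCODE vM21, as whole protein-coding gene spans. Dusp6, a phosphatase that switches ERK off, spans chromosome 10 from 99263231 to 99267489. Spry2 (chromosome 14, 105891947 to 105896819) and Spry4 (chromosome 18, 38586247 to 38601415) encode feedback inhibitors of receptor signalling. Etv4 (chromosome 11, 101769742 to 101785371) and Etv5 (chromosome 16, 22381309 to 22439719) encode transcription factors induced by FGF signalling. The collagen genes Col1a1 (chromosome 11, 94936224 to 94953042) and Col3a1 (chromosome 1, 45311538 to 45349706) encode the main fibrils of dermis and scar. Postn (chromosome 3, 54361109 to 54391037) and Tnc (chromosome 4, 63959785 to 64047015) encode matrix proteins of healing tissue, and Acta2 (chromosome 19, 34241090 to 34255590) encodes the smooth muscle actin of myofibroblasts.

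The first comparison asked what an ERK inhibitor does to the regenerating spiny mouse wound. In epidermal keratinocytes (256 cells against 6852), 10 of 16 measured ERK target and feedback genes were lower and 2 were higher, with a median of −0.69 (−1.01 to 0.15) at percentile 0.01. Etv4 was lower by a ratio of −1.01 (−1.58 to −0.56), Dusp6 by −0.94 (−1.56 to −0.46) and Spry2 by −0.66 (−1.21 to −0.23). Egr1, an immediate early gene of ERK signalling, had 1 UMI against 219 (−3.58, −9.89 to −2.08), while Myc was higher at 1.36 (1.15 to 1.55). Etv5 had 0 UMIs against 67, at least 2.43-fold lower, and Spry4 had 0 against 3. With cells thinned to 1000 UMIs, Dusp6 had 4 UMIs against 102 (interval −1.77 to 1.53), Spry2 4 against 120 (−2.01 to 1.29), Etv4 1 against 128 (−7.51 to 0.30) and Etv5 0 against 19, too few for a direction.

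Of 24 cell cycle genes in the same keratinocytes, 14 were lower and 0 higher with the ERK inhibitor (median −0.61, −0.72 to −0.39, percentile 0). Ube2c, which helps destroy mitotic cyclins, was at −1.21 (−1.43 to −1.02), and the mitotic cyclins Ccnb2 and Ccnb1 were at −1.12 (−1.30 to −0.96) and −1.01 (−1.27 to −0.78). Among 13 wound keratinocyte genes 7 were lower and 2 higher (−0.64, −1.39 to 0.19), with Krt16 lower at −1.39 (−1.47 to −1.31) and the antimicrobial gene S100a8 higher at 1.09 (1.05 to 1.13). That median was −0.37 with thinned cells and no pseudocount, and −0.05 without 2 members at the level of free RNA. Differentiation genes had 0 higher and 3 lower of 14 (−0.29, −0.90 to 0.11), with Flg2, a filaggrin relative of the cornified layer, at 0 UMIs against 476 (at least 17.3-fold lower) and the protease gene Klk7 at −0.96 (−1.1 to −0.84, but −0.28 after thinning). The differentiation median was 0.13 with thinned cells and 0.12 as a mean over cells. Basal genes had 0 higher and 1 lower of 11 (−0.33, −0.55 to 0.09), with Krt5 at −0.46 (−0.47 to −0.45).

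Interferon response genes were higher in 7 and lower in 1 of 13 (0.85, 0.02 to 1.20, percentile 100) in these keratinocytes. Irf1, an interferon-induced transcription factor, was at 1.21 (0.87 to 1.51), and Mx1 at 1.87 (1.52 to 2.20) was at the level of free RNA, as were 8 of the 13 members, with a median of 0.49 over the other five. Of 12 cytokine and chemokine genes 5 were higher and 4 lower (0.08, −2.09 to 2.01), among them the neutrophil chemokines Cxcl5 (39 UMIs against 45, 3.00, 2.34 to 3.64) and Cxcl1 (2.23, 1.98 to 2.47, but 0.94 after thinning). The highest ratios by the naming rule were those of Lcn2 (2.79, 2.60 to 2.97, at the free RNA level), Cyp2b10 (2.38, 2.23 to 2.52) and the protease inhibitor gene Slpi (1.99, 1.87 to 2.10). Mt2, a metallothionein gene, at 1.95 (1.88 to 2.02) and Jun at 1.89 (1.77 to 2.01) followed. The lowest were the hair sheath genes Krt71 (−6.60), Tchh (−5.55) and Krt25 (−3.90), with Vim (−5.10) and Lgals1 (−3.63). These 5 stood at the level of free RNA, meaning under 3 times the lowest other class and over 10-fold below the type that had most. Col1a1 (1 UMI against 697), Col3a1 (0 against 969), Acta2 (2 against 110), Postn (−0.42) and Tnc (−2.46) stood at that level too. Over 21 lists 11 medians were lower by at least 1.5-fold and 1 was higher. Hair follicle genes had a median of −2.40 (0 higher and 8 lower of 12), fibrillar matrix −2.33 (0 and 12 of 19), chondrogenic −2.01 (0 and 6 of 9), angiogenesis −1.73 (0 and 5 of 5) and provisional matrix −1.29 (1 and 7 of 9). Matrix proteases were at −1.13 (2 and 7 of 13), limb patterning genes at −1.03 (1 and 5 of 8) and contractile genes at −0.72 (0 and 6 of 9). In the order given, 7, 16, 6, 2, 4, 7, 3 and 7 members of these lists were at the free RNA level, and without its 3 the limb median was 0.32. Medians within 1.5-fold were those of alternatively activated macrophage genes at −0.37 (1 and 4 of 8), WNT and BMP targets at −0.14 (2 and 5 of 12) and Schwann repair genes at 0.56 (2 and 1 of 5). TGF-beta targets and hypoxia genes had medians of −0.23 (−1.22 to 0.42, 0 higher and 4 lower of 12) and −0.04 (4 and 3 of 18). Dissociation genes were at 0.07 (3 and 3 of 16) and genes for ErbB and FGF ligands and receptors at −0.18 (1 and 5 of 14).

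The fibroblast cluster of the ERK inhibitor library held 5 cells against 161, and 1 cell carried 50.2% of its UMIs. In it 16 of 22 fibrillar matrix genes were higher and 3 lower (0.91, 0.47 to 1.26, percentile 99.9), among them Fbn1 (3.01, 2.62 to 3.36), Dcn (2.42, 2.28 to 2.56) and Col3a1 (1.78, 1.68 to 1.87), with Col1a1 at 0.92 (0.80 to 1.04). That median was −0.070 with thinned cells and no pseudocount, −0.03 as a mean over cells and 0.46 without the deepest cell of each library, and after thinning Col1a1 was at −0.93 and Col3a1 at 0.71. Provisional matrix genes were higher in 5 and lower in 1 of 7 (0.79, −1.01 to 3.62). Postn was at 0.89 (0.67 to 1.1) and Tnc at 1.85 (1.63 to 2.05), but without the deepest cell they were at −0.50 and −3.91. Contractile genes had 1 higher and 4 lower of 7 (−1.09, −2.39 to 1.95, and −0.79 with members at 0 set to their bound), and Acta2 had 0 UMIs against 123 (at least 1.73-fold lower). Matrix proteases and inhibitors had 6 higher and 3 lower of 10 (1.41, −0.86 to 2.19), with Timp1, an inhibitor of matrix proteases, at 2.19 (1.77 to 2.55). For the cell cycle 14 of 18 were lower and 2 higher (−1.46, −1.94 to −0.60), but 12 members had 0 UMIs, and with those at their bound the median was −0.26. Counts of Dusp6 (0 against 8), Spry2 (2 against 18), Etv4 (0 against 14) and Etv5 (1 against 4) were too low for a direction.

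The highest ratios in these fibroblasts were those of Coch (226 UMIs against 1, 11.39, 9.89 to 17.70), Igfbp6 (6.36, 5.77 to 7.07), Apod (6.33, 5.92 to 6.79) and Ifitm1 (5.15, 4.43 to 5.93). Next were Klf2 (5.13, 4.33 to 6.0), Ramp2 (4.72, 4.02 to 5.44), Lama2 (4.35, 3.59 to 5.09) and Itih5 (4.18, 3.40 to 4.91). Coch and Apod also led another cluster annotated as fibroblasts, cluster 34, together with Schwann cell markers. The lowest were Msmp (0 UMIs against 1233, at least 17.3-fold), Fam25c (0 against 1192, at least 16.8-fold), Krt14 (0 against 1189, at least 16.7-fold) and Sfn (0 against 1068, at least 15-fold). They were followed by further keratinocyte genes, Krt1 (1 against 2998, −5.98, −12.29 to −4.50), Krt5 (4 against 5524, −5.54, −7.74 to −4.51), Lgals7 (−5.34, −7.54 to −4.31) and Krt77 (−4.79, −11.09 to −3.31). Keratinocyte markers made up 2.67% of the UMIs of DMSO fibroblasts and 0.0861% of those of ERK inhibitor fibroblasts. These classes thus differed in keratinocyte RNA, which may be free RNA or come from doublets. The part of this RNA in the higher matrix medians was not tested. The cluster annotated by the authors as resident macrophages, cluster 6, held 33 ERK inhibitor cells, and 3 of 8 alternatively activated macrophage genes were higher there and 3 lower (−0.22). In it cytokine genes had 1 higher and 3 lower of 4 (−2.53, and −1.71 with members at 0 at their bound), and cell cycle genes had 2 higher and 12 lower of 15 (−1.43, and −0.53 after thinning). Keratinocyte markers made up 0.0694% of UMIs in these cells and 3.09% with DMSO. Cell cycle genes summed to 3307 CPM in DMSO keratinocytes and 1547 in DMSO cells of cluster 6. Macrophage and monocyte markers outnumbered those of each other type in 5 of the 33 cells and 8 of the 410 DMSO cells. How much keratinocyte RNA adds to these values was not tested.

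The second comparison asked the same of an inhibitor of ErbB2, a receptor of the EGF receptor family through which NRG1 signals. Keratinocytes (4046 cells against 6852) had more RNA of differentiation genes, of which 10 of 15 were higher and 0 lower (0.76, 0.34 to 1.15, percentile 100). Hrnr was at 1.83 (1.75 to 1.92), Klk7 at 1.64 (1.61 to 1.68) and Flg, the filaggrin gene of the cornified layer, at 1.47 (1.45 to 1.49). Basal genes had 6 lower and 0 higher of 11 (−0.65, −0.93 to −0.41, percentile 0), with Krt5 at −0.96 (−0.97 to −0.95), Krt14 at −0.93 (−0.94 to −0.91) and Krt15 at −0.80 (−0.83 to −0.78). Cell cycle genes were lower in 21 of 24 and higher in 0 (−0.80, −0.96 to −0.73, percentile 0), among them Ube2c (−1.19, −1.27 to −1.1), Ccna2 (−1.04, −1.11 to −0.98) and Cdk1 (−1.02, −1.11 to −0.93). Weighted to the DMSO library's mix of keratinocyte clusters, the cell cycle median was −0.20 and the differentiation median 0.17.

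Of 16 ERK target genes 6 were lower and 1 higher with the ErbB2 inhibitor in keratinocytes (−0.41, −0.89 to 0.16, percentile 0.75). Fosl1 was at −1.69 (−2.46 to −1.06), Ccnd1, which drives entry into the cell cycle, at −1.04 (−1.11 to −0.97), Dusp6 at −0.89 (−1.12 to −0.68) and Spry2 at −0.80 (−1.01 to −0.59). Etv4 was at 0.51 (0.35 to 0.66), Etv5 was at −0.57 (−1.21 to 0.01), and Spry4 had 1 UMI against 3. Cytokine genes had 7 lower and 0 higher of 12 (−0.72, −1.03 to −0.10), with the alarmin gene Il33 at −1.03 (−1.15 to −0.93). TGF-beta targets had 6 lower and 0 higher of 12 (−0.56, −0.96 to 0.09), with Ccn1 at −1.99 (−2.23 to −1.78). Wound genes had 6 lower and 1 higher of 13 (−0.52, −1.29 to −0.29), with S100a9 at −2.06 (−2.13 to −2.0) and the EGF receptor ligand gene Hbegf higher at 1.75 (1.48 to 2.04). Interferon genes had 1 higher and 3 lower of 15 (−0.30, −0.48 to 0.32), dissociation genes 5 and 4 of 17 (0.01, −0.31 to 0.63), ligands and receptors 2 and 3 of 15 (−0.11), and hypoxia genes 0 and 4 of 18 (−0.20). Fos was at −1.38 (−1.49 to −1.27).

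By the naming rule the highest ratios in ErbB2 inhibitor keratinocytes were those of Wfdc17 (2.31, 2.21 to 2.41) and Asprv1 (2.18, 2.15 to 2.22), a protease gene of the granular layer. Lce1b (2.01, 1.90 to 2.12) and Lce1f (1.94, 1.87 to 2.02), genes of the cornified envelope, and the claudin gene Cldn4 (1.96, 1.85 to 2.07) followed. The lowest were Krt71 (−6.13, −6.58 to −5.76), Tchh (−5.91), Krt25 (−4.94) and S100a3 (−1.58), all at the free RNA level, and S100a9. Col1a1 (0.06), Col3a1 (−0.32), Acta2 (−0.89), Postn (−0.96) and Tnc (−1.09) were at the free RNA level in these cells. Over 21 lists 8 medians were lower by at least 1.5-fold and 1 was higher, and not all of these lists are given here.

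In the fibroblast cluster (131 cells against 161) 8 of 24 fibrillar matrix genes were higher and 0 lower with the ErbB2 inhibitor (0.45, 0.21 to 0.64, percentile 100). Col5a2 was at 0.92 (0.80 to 1.03), Col3a1 at 0.35 (0.31 to 0.40), Postn at 0.36 (0.28 to 0.43) and Col1a1 at 0.06 (0.02 to 0.11). Provisional matrix genes had 3 higher and 0 lower of 9 (0.50, 0.31 to 0.86), with Has2, a hyaluronan synthase gene, at 1.04 (0.69 to 1.41) and Tnc at 0.45 (0.34 to 0.55). Contractile genes had 2 higher and 0 lower of 7 (0.40, −0.11 to 0.97), with Tagln at 0.94 (0.79 to 1.1) but Acta2 at −0.11 (−0.50 to 0.27), and proteases and inhibitors 3 and 0 of 14 (0.51, 0.17 to 0.70). Cell cycle genes had 5 lower and 0 higher of 21 (−0.39, −0.57 to −0.09), with Ube2c at −1.1 (−1.89 to −0.42). Among cells whose fibroblast markers outnumbered those of each other type, that median was 0.27 and Ube2c was at 0.66. ERK targets had 0 higher and 0 lower of 5 (−0.14), with Dusp6 at 8 UMIs against 8, Spry2 at 9 against 18, Etv4 at 10 against 14 and Etv5 at 4 against 4.

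Highest in ErbB2 inhibitor fibroblasts was Ibsp (89 UMIs against 1, 5.61, 4.08 to 11.91), the bone sialoprotein gene, which spans chromosome 5 from 104299171 to 104311469. Next came Dlk1 (60 against 3, 4.05, 2.82 to 6.75), Igfbp6 (2.38, 1.82 to 3.08) and Pi16 (2.24, 1.5 to 3.23), and then the collagen lysyl hydroxylase gene Plod2 (2.09, 1.38 to 3.01), Ecrg4 (2.01, 1.63 to 2.45), Mest (1.68, 1.04 to 2.45) and the growth factor gene Igf2 (1.61, 1.07 to 2.22). Dlk1, Mest and Igf2 are imprinted genes active in fetal mesenchyme. Lowest were Msmp (2 against 1233, −8.57, −12.20 to −7.30), Krt71 (0 against 59, at least 18.2-fold), Tchh (1 against 75), Krt25 (4 against 144) and the MHC class II gene H2-Aa (−3.06, −4.59 to −2.11). The keratins of epidermis followed, with Krt5 (−2.93, −3.05 to −2.82), Krt14 (−2.87, −3.14 to −2.63) and Krt77 (−2.83, −3.08 to −2.61). Keratinocyte markers made up 1.22% of the UMIs of ErbB2 inhibitor fibroblasts, against 2.67% with DMSO. Keratinocyte differentiation genes summed to 22955 CPM in DMSO fibroblasts and 86978 in DMSO keratinocytes. Such RNA lowers the CPM of fibroblast genes in the DMSO cells. How much of the higher matrix medians comes from this was not tested.

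In cluster 6 (187 cells against 410) with the ErbB2 inhibitor, cytokine genes had 5 lower and 1 higher of 6 (−1.34, −2.96 to 1.29), with Il1b at −1.44 (−2.36 to −0.74) and the monocyte chemokine gene Ccl8 higher at 1.29 (1.02 to 1.56). Alternatively activated macrophage genes had 4 higher and 1 lower of 9 (0.05, −0.36 to 1.11), with the lipid receptor gene Trem2 at 1.59 (1.07 to 2.15). Cell cycle genes had 14 lower and 0 higher of 18 (−0.86, −1.44 to −0.68), and interferon genes 3 lower and 1 higher of 10 (−0.16). The T cell chemokine gene Ccl17 was highest (164 UMIs against 12, 4.41, 3.67 to 5.50), followed by Mtss1 (2.42, 1.61 to 3.47), the complement gene C1qb (2.20, 2.04 to 2.37), B3gnt8 (2.20, 1.35 to 3.25) and Ndrg4 (2.17, 1.35 to 3.19). Lowest were Krt25 (2 against 299), Tchh (1 against 196), Krt71 (2 against 142), S100a3 (4 against 69) and Krt17 (−3.07, −3.60 to −2.64), all genes of hair or epidermis, and keratinocyte markers made up 2.22% of the UMIs here against 3.09% with DMSO. Dusp6 was at 0.28 (−0.24 to 0.78).

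The third comparison took an inhibitor of the FGF receptors. Keratinocytes (2088 cells against 6852) had 8 of 15 differentiation genes higher and 0 lower (0.68, 0.12 to 1.28, percentile 100), with Hrnr at 1.60 (1.5 to 1.69), Flg2 at 1.40 (1.23 to 1.58) and Flg at 1.32 (1.30 to 1.34). Cell cycle genes had 15 lower and 0 higher of 24 (−0.64, −0.75 to −0.54, percentile 0), with Mcm2 and Mcm6, subunits of the replicative helicase, at −1.01 (−1.22 to −0.81) and −0.94 (−1.07 to −0.83). ERK targets had 1 higher and 2 lower of 16 (0.12, −0.37 to 0.44), with Egr1 at 1.04 (0.77 to 1.31) and Dusp6 at 0.55 (0.37 to 0.74). Spry2 was at −0.31 (−0.54 to −0.10), Etv4 at −0.59 (−0.82 to −0.37) and Etv5 at −1.22 (−2.25 to −0.46), and Spry4 had 2 UMIs against 3. Dissociation and immediate early genes, which tissue handling also raises, were higher in 9 and lower in 0 of 17 (0.60, 0.43 to 1.30, percentile 100). Fosb was at 2.57 (2.41 to 2.75), Fos at 2.14 (2.08 to 2.21), Dusp1 at 1.52 (1.47 to 1.57) and Jun at 1.30 (1.21 to 1.39). Weighted to the DMSO mix of clusters, the differentiation median was 0.09 and the cell cycle median −0.16.

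Among ligand and receptor genes in FGFR inhibitor keratinocytes 3 were higher and 2 lower of 15 (−0.05), the former being the EGF receptor ligand genes Btc (92 UMIs against 33, 2.41, 1.85 to 3.06), Hbegf (1.29, 0.97 to 1.62) and Areg (1.11, 0.84 to 1.37). Basal genes had 0 higher and 1 lower of 11 (−0.20, −0.49 to −0.04), wound genes 2 and 3 of 13 (−0.08, −0.77 to 0.44) and interferon genes 2 and 2 of 14 (0.02). For cytokines the counts were 2 and 3 of 12 (0.12), for TGF-beta targets 1 and 2 of 12 (−0.28) and for hypoxia genes 0 and 1 of 18 (−0.26, −0.34 to −0.20). Krt23 was among the highest by the rule (1.37, 1.29 to 1.46), and Tchh (−4.93), Krt71 (−4.88), Krt25 (−3.48), Vim (−1.86) and Cd74 (−1.66), all at the free RNA level, were lowest. Col1a1 (−1.62), Col3a1 (−1.23), Acta2 (−0.63), Postn (−0.31) and Tnc (−1.07) were at the free RNA level as well. Over 21 lists 8 medians were lower by at least 1.5-fold and 2 were higher, and not all of these lists are given here.

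In the fibroblast cluster (38 cells against 161) contractile genes had 4 higher and 0 lower of 7 with the FGFR inhibitor (0.65, 0.10 to 1.5, percentile 99.97), with Acta2 at 1.5 (1.1 to 1.89) and Tagln at 1.19 (1.0 to 1.38). Fibrillar matrix genes had 6 higher and 1 lower of 23 (0.38, 0.23 to 0.52, percentile 100), with Sparc at 0.71 (0.64 to 0.78), Col3a1 at 0.49 (0.43 to 0.56), Col1a1 at 0.34 (0.28 to 0.40) and Postn at 0.30 (0.18 to 0.41). Provisional matrix genes had 4 higher and 1 lower of 8 (0.59, −1.51 to 0.91), with Tnc at 0.70 (0.56 to 0.83) and Ptx3 at −1.51 (−2.23 to −0.95). Proteases and inhibitors had 5 lower and 0 higher of 11 (0.14, −1.71 to 0.53), cell cycle genes 1 lower and 2 higher of 21 (0.10, −0.22 to 0.40) and ERK targets 0 and 0 of 5 (0.50). Counts were low for Dusp6 (6 UMIs against 8), Spry2 (6 against 18), Etv4 (8 against 14) and Etv5 (2 against 4). The fibrillar median was 0.23 among cells whose own markers were highest and 0.10 without the cells scored highest as doublets.

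Highest in FGFR inhibitor fibroblasts were Fos (2.29, 1.67 to 2.94), Ifitm1 (2.15, 1.41 to 2.94), Igfbp6 (1.64, 0.80 to 2.48), Itih5 (1.63, 0.91 to 2.34), Prss23 (1.51, 1.09 to 1.92), Tppp3 (1.51, 0.69 to 2.30), Acta2 and Serpina12 (1.49, 0.78 to 2.17). Serpina12 rested on 1 cell, with a ratio of −1.53 without the deepest cell of each library. Lowest were Msmp (0 UMIs against 1233, at least 122-fold), Krt25 (1 against 144), Tchh (2 against 75) and Clca3a2 (−2.38, −3.59 to −1.60). Then came the desmosome genes Jup (−2.37, −3.32 to −1.71) and Dsp (−2.23, −2.92 to −1.71), the hemidesmosome gene Col17a1 (−2.36, −3.34 to −1.68) and Stfa3 (−2.22, −2.73 to −1.80). Keratinocyte markers made up 1.49% of the UMIs of these fibroblasts, against 2.67% with DMSO. How much of the higher contractile and matrix medians comes from this difference was not tested. Igfbp6 was thus among the 8 highest in fibroblasts with each inhibitor, all against the same DMSO library.

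With the FGFR inhibitor, cluster 6 (115 cells against 410) had 6 of 10 interferon genes lower and 0 higher (−0.72, −2.20 to −0.08, percentile 0), with Ifitm3 at −2.20 (−2.40 to −2.02). Alternatively activated macrophage genes had 6 higher and 1 lower of 10 (1.12, −0.58 to 1.60, percentile 100), with the scavenger receptor gene Cd163 at 2.20 (1.26 to 3.29) and Trem2 at 1.60 (1.02 to 2.19), but the median was −0.08 after thinning. Highest were Rgs1 (56 UMIs against 3, 5.13, 3.90 to 7.84), the chemokine genes Ccl20 (3.75, 3.17 to 4.49) and Ccl12 (2.84, 2.15 to 3.67), Selenop (2.80, 2.01 to 3.77) and Fcrls (2.75, 1.90 to 3.81), with Ccl8 at 2.66 (2.42 to 2.91). Lowest were Krtcap3 (0 against 72, at least 9.76-fold), Krt71 (3 against 142), Tchh (5 against 196), Adh7 (−3.47, −5.67 to −2.39) and Jup (−3.38, −4.32 to −2.74), and keratinocyte markers made up 1.28% of UMIs here against 3.09% with DMSO. Cytokine genes had 2 higher and 2 lower of 5 (−0.16), cell cycle genes 6 and 3 of 17 (0.20), and Dusp6 was at 0.56 (−0.00 to 1.09).

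**Figure D1:**
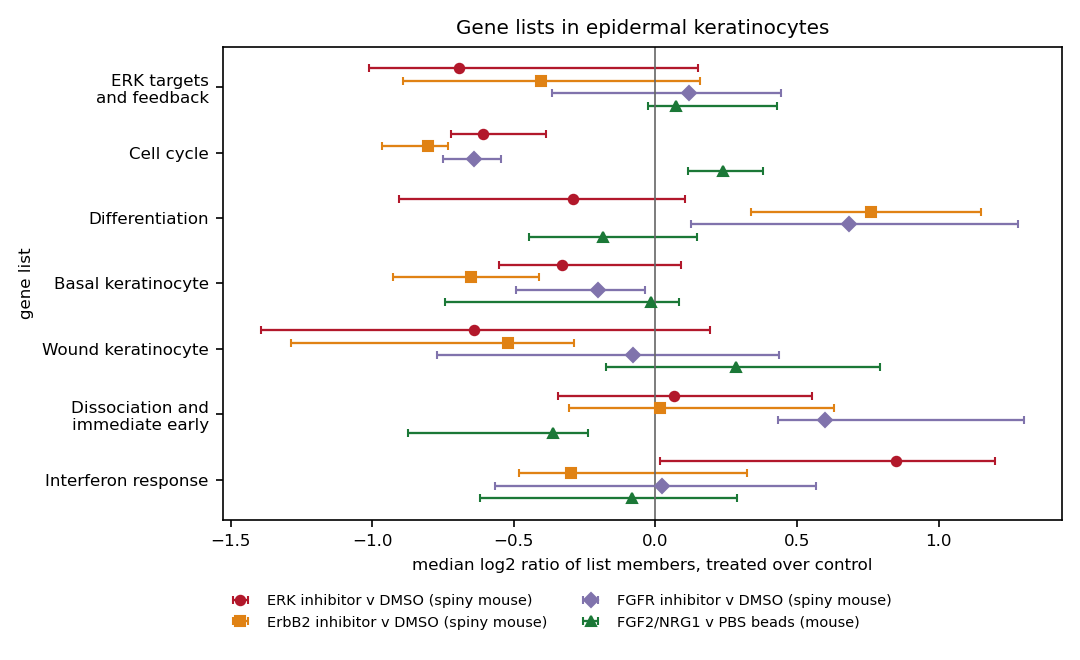
Median log2 ratio of treated over control for gene lists in epidermal keratinocytes (horizontal axis, log2 ratio), with 1 marker per comparison and lists on the vertical axis. Bars are 95% intervals of the median over list members. The cell cycle medians of the 3 inhibitors lie at −0.61, −0.80 and −0.64 and that of FGF2 and NRG1 at 0.24.

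The fourth comparison asked what added FGF2 and NRG1 do in the scarring wound of the laboratory mouse. In the fibroblast cluster (153 cells against 32 with PBS) 23 of 27 fibrillar and scar matrix genes were lower and 0 higher (−1.22, −2.06 to −0.82, percentile 0). Thbs1, which encodes an activator of TGF-beta, was at −4.03 (−5.13 to −3.09), the collagen cross-linking enzyme gene Loxl2 at −2.77 (−3.07 to −2.47), Col1a1 at −2.52 (−2.58 to −2.47) and Col3a1 at −2.34 (−2.39 to −2.29). The small proteoglycan genes Lum (0.04, −0.13 to 0.22) and Bgn (0.45, 0.28 to 0.63) were among the 4 members within 1.5-fold. Postn was at −2.18 (−2.30 to −2.05), and contractile genes had 4 lower and 2 higher of 9 (−0.05, −1.34 to 0.66) with Acta2 at −1.77 (−2.16 to −1.34). With cells thinned to 1000 UMIs Col1a1 was at −1.66 (−1.84 to −1.48), Col3a1 at −1.62 (−1.77 to −1.47), Postn at −1.28 (−1.67 to −0.87) and Loxl2 at −2.05. The fibrillar median was −0.76 as a mean over cells, −1.10 after thinning and −0.59 over both clusters annotated as fibroblasts. Keratinocyte markers made up 0.169% of UMIs in these fibroblasts and 0.475% with PBS.

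**Figure D2:**
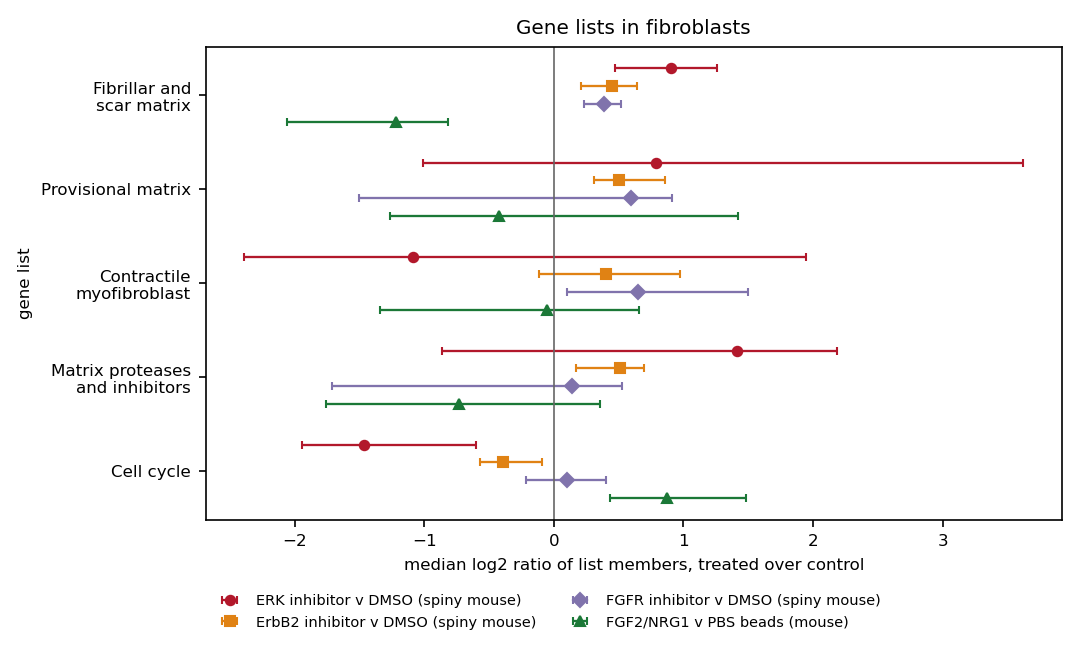
Median log2 ratio of treated over control for gene lists in the fibroblast cluster (horizontal axis, log2 ratio), with 1 marker per comparison and lists on the vertical axis. Bars are 95% intervals of the median over list members. The fibrillar matrix medians lie at 0.91, 0.45 and 0.38 for the ERK, ErbB2 and FGFR inhibitors and at −1.22 for FGF2 and NRG1, while the ERK inhibitor value rests on 5 cells and is −0.03 as a mean over cells. DMSO fibroblasts held more keratinocyte RNA than those of each inhibitor, and its part in the inhibitor medians was not tested.

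Cell cycle genes were higher in 14 and lower in 0 of 21 in FGF2 and NRG1 fibroblasts (0.87, 0.43 to 1.49, percentile 100), with the proliferation marker Mki67 at 2.68 (291 UMIs against 4, 1.63 to 4.89). ERK targets had 6 higher and 3 lower of 13 (0.49, −0.81 to 1.19, percentile 99.6). Hmga2, a chromatin gene active in embryos that spans chromosome 10 from 120361275 to 120476469, was higher at 4.08 (461 UMIs against 2, 2.80 to 7.71). Ccnd1 was higher too (1.84, 1.21 to 2.74) and Egr1 lower (−2.89, −3.68 to −2.08). Dusp6 (40 UMIs against 2, 0.59, −0.81 to 4.23), Etv4 (0.75, −0.27 to 2.66), Spry4 (24 against 1, 0.46, −1.22 to 6.76), Spry2 (−0.18, −1.20 to 1.52) and Etv5 (−0.25, −1.16 to 1.17) had intervals that included 0, so no difference was detectable at this depth. Chondrogenic genes had 7 higher and 2 lower of 11 (1.34, −0.92 to 2.90, and 1.11 with members at 0 at their bound). The cartilage matrix gene Comp was at 2.41 (144 UMIs against 2, 1.11 to 6.05) and the chondrocyte transcription factor gene Sox5 at 100 UMIs against 0 (at least 3.67-fold higher). Hypoxia and glycolysis genes had 7 higher and 4 lower of 14 (0.73, −0.97 to 1.58), with Ldha at 1.78 (1.35 to 2.31), and dissociation genes had 9 lower and 1 higher of 13 (−1.39, −2.15 to −0.39). Chondrocyte markers made up 0.0549% of UMIs in these fibroblasts and 0.0436% with PBS.

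Proteases and inhibitors had 7 lower and 2 higher of 14 in these fibroblasts (−0.73, −1.76 to 0.36), with Timp1 at 1.93 (1.57 to 2.38). Provisional matrix genes had 5 lower and 4 higher of 12 (−0.42, −1.27 to 1.42), and TGF-beta targets 6 and 2 of 14 (−0.26, −1.18 to 0.48). Tnc was at −0.58 (−0.87 to −0.25) but did not keep that direction, being at 0.57 with thinned cells (46 UMIs against 5, −0.52 to 2.49), 0.53 as a mean over cells and 1.55 in cells under 10% mitochondrial UMIs. Highest by the rule was Spp1 (9991 UMIs against 14, 6.20, 5.55 to 7.17), the osteopontin gene, which spans chromosome 5 from 104435118 to 104441050. Next came Lbhd2 (329 against 1, 4.18, 2.69 to 10.49), Hmga2, Slpi (434 against 3, 3.58, 2.44 to 6.28) and Cda (206 against 1, 3.51, 2.01 to 9.81). They were followed by the cell cycle inhibitor gene Cdkn2a (129 against 0, at least 4.73-fold), Cytl1 (101 against 0, at least 3.70-fold) and Sox5. Among the lowest were S100a8 (−5.45, −6.18 to −4.87), S100a9 (−4.31, −4.82 to −3.85), Lpl (−4.12, −4.98 to −3.36), Gpnmb (−3.89, −4.78 to −3.1), Clec3b (−3.86, −4.25 to −3.48) and the hedgehog receptor gene Ptch1 (−3.84, −4.61 to −3.13). Of the 32 PBS fibroblasts 1 carried 7.81% of the UMIs.

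**Figure D3:**
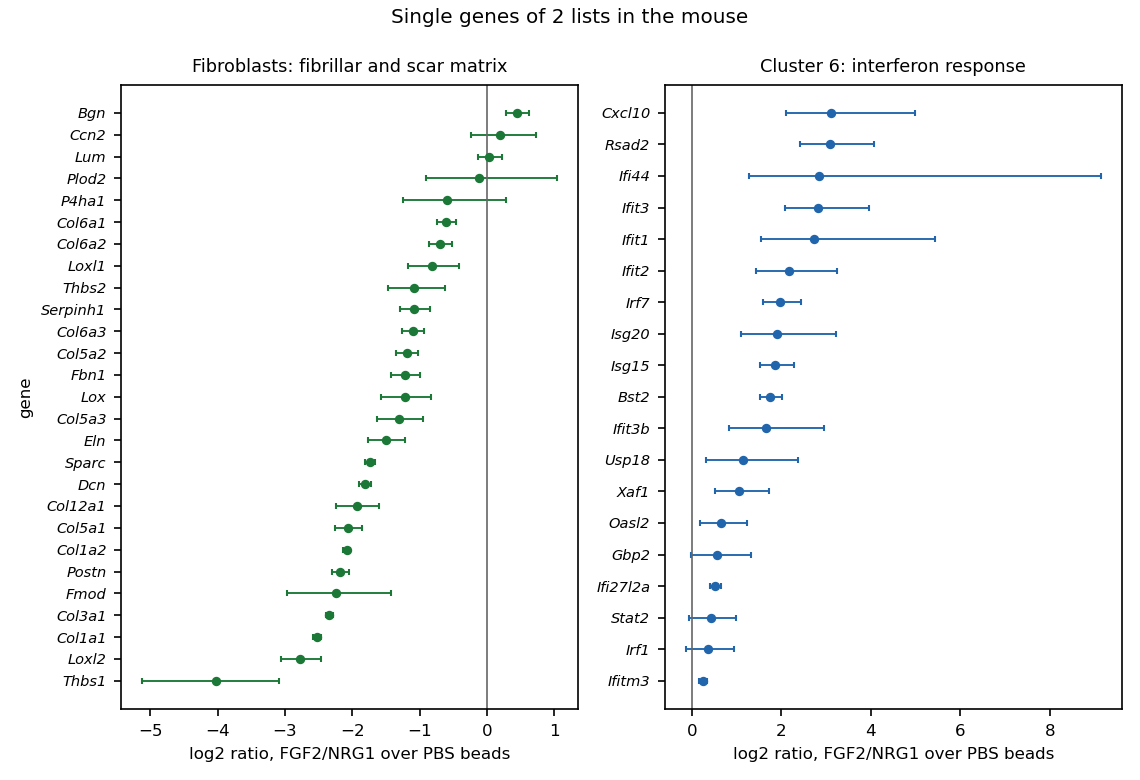
Log2 ratio of FGF2 and NRG1 over PBS (horizontal axis) for single genes (vertical axis), with fibrillar matrix genes in the fibroblast cluster in one panel and interferon response genes in cluster 6 in the other. Bars are 95% counting intervals, and 19 of the 20 interferon genes are drawn. In fibroblasts 23 of 27 genes lie at or beyond 1.5-fold below PBS, and in cluster 6 there are 14 interferon genes at or beyond 1.5-fold above it.

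In cluster 6 (566 cells against 107 with PBS) interferon response genes were higher in 14 and lower in 0 of 20 with FGF2 and NRG1 (1.70, 0.56 to 2.16, percentile 100). Cxcl10, a chemokine gene induced by interferon, was at 3.1 (192 UMIs against 5, 2.11 to 5.00). The antiviral genes Rsad2 and Ifit3 were at 3.09 (2.43 to 4.07) and 2.81 (2.07 to 3.95). After thinning Cxcl10 was at 1.56 and Ifit3 at 1.58. Alternatively activated macrophage genes had 6 higher and 1 lower of 16 (0.41, −0.25 to 1.79), with Trem2 at 2.03 (1.63 to 2.52), and cytokine genes 6 and 2 of 12 (0.46, −0.34 to 1.92). Highest was Ccl8 (851 UMIs against 0, at least 75.7-fold), which spans chromosome 11 from 82115185 to 82116799. Next were Cox6a2 (291 against 0, at least 25.9-fold), Ccl12 (142 against 0, at least 12.6-fold), the folate receptor gene Folr2 (137 against 0, at least 12.2-fold) and Klk1 (254 against 3, 4.09, 2.93 to 6.78). Lowest were Tchh (−3.33, −3.51 to −3.15), the eosinophil chemokine gene Ccl24 (−2.55, −2.93 to −2.18), Sprr1a (−2.51, −2.90 to −2.15), Mgl2 (−2.21, −2.70 to −1.73) and Crct1 (−1.97, −2.49 to −1.46). Of these all but Ccl24 were above 0 among cells whose own markers were highest. Dusp6 was at −0.70 (−1.11 to −0.26). Cell cycle genes had 8 higher and 0 lower of 14 (1.03), but the median was −0.10 without the 9 members at the free RNA level, and keratinocyte markers made up 0.212% of UMIs against 0.315% with PBS.

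Mouse keratinocytes (955 cells against 1035) had smaller differences in the lists given here. Over 21 lists 2 medians, not given here, were higher by at least 1.5-fold and 0 were lower. Cell cycle genes had a median of 0.24 (0.12 to 0.38, percentile 100) with 1 of 25 higher and 1 lower. Mcm2 was at 0.61 (0.30 to 0.92, but −0.14 after thinning) and Mki67 at 0.44 (0.34 to 0.53), and the median was 0.02 with clusters weighted as with PBS. Differentiation genes had 1 higher and 2 lower of 16 (−0.18, −0.45 to 0.15), with Flg at 2.54 (2.24 to 2.86) and the cornified envelope gene Lor at −1.21 (−1.30 to −1.12), though Lor was at 0.10 as a mean over cells. Basal genes had 2 lower and 0 higher of 11 (−0.02, −0.74 to 0.08), with Cxcl14 at −1.06 (−1.18 to −0.94) and Krt15 at −0.74 (−0.76 to −0.72). Cytokine genes had 5 higher and 2 lower of 12 (0.46, 0.02 to 2.73), including Ccl8 (52 UMIs against 3, 4.25, 3.01 to 6.96) and Cxcl2 (59 against 12, 2.73, 1.91 to 3.85), and wound genes 3 and 1 of 14 (0.28, −0.17 to 0.79). The cytokine median was −0.22 after thinning, with 3 members left. ERK targets had 1 higher and 2 lower of 15 (0.07, −0.03 to 0.43), with Dusp6 at 0.64 (0.09 to 1.21, at the free RNA level) and Spry2 at 0.03 (−0.42 to 0.46). Etv4 was at 0.47 (−0.37 to 1.30), Etv5 at 0.43 (−0.19 to 1.04) and Spry4 at 0 UMIs against 8 (1.86-fold lower by the floor of 3 UMIs, without the counting error of the 8). Dissociation genes had 6 lower and 0 higher of 20 (−0.36, −0.87 to −0.24, percentile 0), with Fos at −2.80 (−3.30 to −2.39).

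Among the highest in mouse keratinocytes were Skint9 (2.11, 1.93 to 2.30) and the genes at the free RNA level Vim (2.30, 2.08 to 2.53), Krt71 (2.17), Krt25 (1.88) and Tchh (1.38). Lowest were Lce1m (−2.07, −2.24 to −1.91), Lce1l (−2.07, −2.23 to −1.92), Lce1i (−2.03, −2.29 to −1.80), Dusp1 (−1.58, −1.83 to −1.35) and Hpgds (−1.51, −1.76 to −1.27), and all 3 Lce1 genes were above 0 among cells whose own markers were highest. Acta2 was at 2.82 (2.28 to 3.49), Postn at 0.18 (0.08 to 0.29), and Col1a1 (0.96, but −0.43 after thinning), Col3a1 (1.36) and Tnc (0.35) were at the free RNA level. Fibroblast, endothelial and macrophage markers made up 0.763% of keratinocyte UMIs with FGF2 and NRG1 and 0.626% with PBS. Medians were −0.08 (0 higher and 2 lower of 11) for interferon genes, −0.07 (2 and 1 of 12) for TGF-beta targets, −0.04 (0 and 0 of 17) for hypoxia genes and 0.08 (1 and 0 of 13) for ligands and receptors. Haemoglobin genes had a median of 1.05 (4 and 0 of 4). In spiny mouse keratinocytes it was −0.55 (0 and 1 of 3), −0.82 (0 and 2 of 3) and −1.28 (0 and 3 of 3) with the ERK, ErbB2 and FGFR inhibitors. Over all interfollicular clusters the ErbB2 inhibitor value for haemoglobin was 0.83.

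Shares of cells were compared within a species. With FGF2 and NRG1 chondrocytes made up 4.86% of cells (exact 95% binomial interval 4.29 to 5.48) against 1.17% (0.824 to 1.62) with PBS, and the fibroblast cluster 3.00% (2.55 to 3.5) against 1.04% (0.715 to 1.47). Cluster 6 made up 11.1% (10.2 to 12) against 3.49% (2.87 to 4.20), and T cells 2.66% (2.24 to 3.14) against 1.17% (0.824 to 1.62). Shares were also larger for endothelium, at 18.4% (17.4 to 19.5) against 11.3% (10.2 to 12.5), and for cluster 7, which neutrophil genes lead, at 12% (11.1 to 12.9) against 10.0% (8.98 to 11.1). Epidermal keratinocytes were fewer, at 18.7% (17.6 to 19.8) against 33.8% (32.1 to 35.5). Types are those the authors assigned from expression, and genes that mark them, such as Col1a1 in fibroblasts, themselves differed between these libraries.

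In the spiny mouse, epidermal keratinocytes made up 44.6% (43.8 to 45.4) of DMSO cells, 40.6% (36.7 to 44.5) with the ERK inhibitor, 38.1% (37.1 to 39.0) with the ErbB2 inhibitor and 43.7% (42.3 to 45.1) with the FGFR inhibitor. Interfollicular clusters left out of that class made up 10.4%, 5.39%, 15% and 9.01% in the same order, 1.37% with PBS and 1.35% with FGF2 and NRG1. Cluster 7 made up 1.48% (1.29 to 1.68) of DMSO cells and 8.72% (6.63 to 11.2) of ERK inhibitor cells, against 0.969% (0.791 to 1.17) and 1.86% (1.5 to 2.29) with the ErbB2 and FGFR inhibitors. For cluster 6 the shares were 2.67% (2.42 to 2.94), 5.23% (3.63 to 7.27), 1.76% (1.52 to 2.03) and 2.40% (1.99 to 2.88), for the fibroblast cluster 1.05% (0.893 to 1.22), 0.792% (0.258 to 1.84), 1.23% (1.03 to 1.46) and 0.795% (0.563 to 1.09). Of epidermal keratinocytes, those in clusters annotated as cycling made up 19.6% (18.7 to 20.6) with DMSO and 12.9% (9.04 to 17.6), 12.3% (11.3 to 13.4) and 13.5% (12.1 to 15) with the inhibitors, and 18.7% (16.4 to 21.3) with PBS against 19.5% (17.0 to 22.1) with FGF2 and NRG1. Those clusters are themselves defined by cell cycle genes. Chondrocytes were at 1.94% (1.73 to 2.17), 0.792% (0.258 to 1.84), 1.28% (1.07 to 1.51) and 1.78% (1.42 to 2.19), and endothelium at 6.36% (5.98 to 6.76), 6.97% (5.11 to 9.25), 4.05% (3.69 to 4.45) and 5.02% (4.42 to 5.68). Cluster 21, a suprabasal cluster, held 0.970% (0.821 to 1.14) of DMSO cells and 6.34% (5.88 to 6.82) with the ErbB2 inhibitor, and as 1 library held most of it, it is not read as a cell type.

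**Figure D4:**
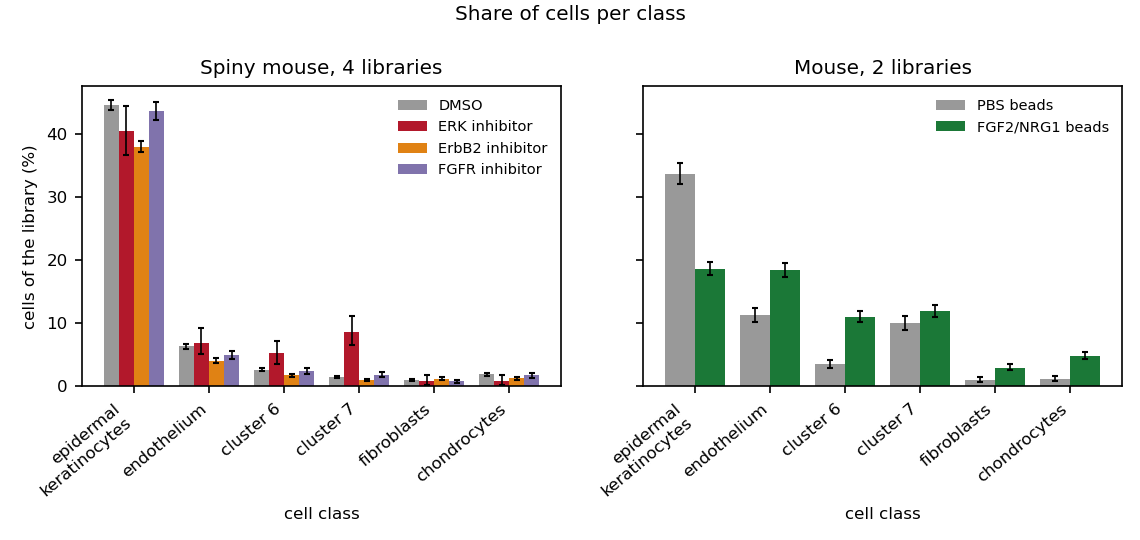
Share of cells (percent of all cells of a library, vertical axis) in each of several classes for the 6 libraries. Bars are exact 95% binomial intervals. Chondrocytes lie at 4.86% with FGF2 and NRG1 against 1.17% with PBS, and at 1.94% with DMSO against 0.792%, 1.28% and 1.78% with the ERK, ErbB2 and FGFR inhibitors.

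A further question was whether blocking ERK in the spiny mouse and adding growth factors in the mouse moved genes in opposite ways. Across 1469 genes in fibroblasts the ERK inhibitor ratio and the FGF2 and NRG1 ratio had a Spearman correlation of −0.274 and a Pearson correlation of −0.208. In keratinocytes the values over 7871 genes were −0.0985 and −0.196, and the latter was −0.0542 without genes at the free RNA level. Against the same mouse ratios the ErbB2 inhibitor gave Spearman correlations of −0.168 in fibroblasts and −0.0476 in keratinocytes, and the FGFR inhibitor −0.133 and −0.118. These pairs share no library, and genes are not independent replicates. The fibroblast values rest on 32 PBS cells and, for the ERK inhibitor, on 5 cells, of which the deepest carried 50.2% of UMIs. In those 5 cells the fibrillar matrix median was −0.03 as a mean over cells. The correlations were not computed as a mean over cells, with thinned cells or without the deepest cell. The ERK inhibitor value in fibroblasts thus cannot decide the question of opposite ways. With at least 300 UMIs per gene the Spearman values in fibroblasts were −0.430 for the ERK inhibitor (464 genes), −0.328 for the ErbB2 inhibitor (641 genes) and −0.260 for the FGFR inhibitor (525 genes).

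Ratios of different inhibitors share the DMSO library, which adds correlation without any effect. In keratinocytes the ErbB2 and FGFR inhibitor ratios had a Spearman correlation of 0.653 and a covariance of 0.176 over 9443 genes, against 0.356 and 0.00597 for unchanged libraries simulated in 100 draws. The ERK inhibitor had 0.442 with the ErbB2 inhibitor (simulated 0.187; covariance 0.169, simulated 0.00460; 9041 genes) and 0.443 with the FGFR inhibitor (simulated 0.164; covariance 0.165, simulated 0.00469; 9040 genes). Genes lower with both numbered 427 for ErbB2 and FGFR, 392 for ERK and ErbB2 and 341 for ERK and FGFR, against 71.0, 82.7 and 55.7 for independent lists, and genes higher with both 225, 132 and 89 against 17.7, 35.3 and 24.7. Fibroblasts gave correlations of 0.415, 0.399 and 0.339 in that order (simulated 0.308, 0.120 and 0.0885), with covariances of 0.139, 0.269 and 0.223 (simulated 0.0131, 0.00946 and 0.00960). There, genes lower with both numbered 56, 73 and 72 against 5.86, 22.8 and 24.1, and genes higher with both 32, 46 and 39 against 6.24, 17.5 and 15.5. Part of each excess may come from the shared control, since 1 DMSO library cannot be split. The independent lists ignore that control, and the simulated libraries hold counting error only, so an excess over them does not show a shared effect. Keratinocyte markers made up 2.67% of UMIs in DMSO fibroblasts, against 0.0861%, 1.22% and 1.49% with the ERK, ErbB2 and FGFR inhibitors. These correlations were not computed without genes at the free RNA level.

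The vehicle libraries of the species were set side by side without a ratio, because species, vehicle and day all differ. Cell cycle genes summed to 3307 CPM in DMSO keratinocytes and 2048 in PBS keratinocytes, ERK targets to 437 and 405, interferon genes to 6136 and 671, and differentiation genes to 86978 and 29853. Fibrillar matrix genes made up 49840.5 CPM in DMSO fibroblasts and 98639 in PBS fibroblasts. These fibroblasts also differed in keratinocyte RNA, with differentiation genes at 22955 CPM with DMSO and 3108 with PBS. The PBS value rests on 32 cells, and spiny mouse genes may be undercounted, so the matrix values are not read as a species difference.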

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

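No difference below was tested, and the clusters set side by side here were chosen after the data were seen. With the FGFR inhibitor the interferon response list moved in opposite ways in the myeloid clusters compared by number. In cluster 6 its median was −0.72 over 10 members, 0 of them higher and 6 lower, while in cluster 7 it was 0.60 over 5 members, 3 of them higher and 0 lower. RNA of keratinocyte markers was 3.09% of UMIs with DMSO and 1.28% with the inhibitor in cluster 6, and 4.81% and 2.63% in cluster 7, and interferon genes summed to 6136 CPM in DMSO keratinocytes and 3192 in DMSO cells of cluster 6. Each value comes from 1 pair of libraries and the difference between the clusters was not tested.

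Signals of other cell types stood out in clusters that the comparisons did not use. Schwann cell markers, genes of the cells that wrap nerve fibres, made up 0.543% of UMIs (1401 UMIs in 48 cells) in PBS cells of cluster 34, annotated as fibroblasts, and 0.342% with FGF2 and NRG1, against 0.00623% in PBS cells of cluster 32. In the spiny mouse the share in cluster 34 was 0.00147% (4 UMIs in 136 cells) with DMSO, 0.00121% (3 in 143) with the ErbB2 inhibitor and 0.0200% (21 in 59) with the FGFR inhibitor, although the cluster was kept out of fibroblasts in both species. Mast cell markers made up 1.90% of UMIs (2365 UMIs in 94 cells) in DMSO cells of cluster 45, annotated as resident macrophages, against 0.00983% in cluster 6. With the ErbB2 inhibitor the share was 0.164% (54 UMIs in 29 cells), and 17 cells with FGF2 and NRG1 held 0 such UMIs. Melanocyte markers made up 0.00345% of UMIs in DMSO cells of cluster 23, a cluster with no type given, which is 17 UMIs in 316 cells, against 0.000177% in cluster 32. Other libraries had 0.141% (67 UMIs in 18 cells) with the FGFR inhibitor, 0.0682% (40 in 59) with FGF2 and NRG1, 0.00586% (2 in 29) with PBS and 0.00243% (15 in 396) with the ErbB2 inhibitor. No explanation of these was tested.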

How the results depend on the processing

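The alternatives without the cells of highest doublet score, over the whole annotated type, without the deepest cell, without genes at the free RNA level, with the control library's mix of clusters and without a pseudocount were tests chosen after seeing the data, and the others were set in advance. Of values that answer a comparison, alternatives chosen in advance left 229 within their interval, or the shift allowed where there was none, moved 19 past it and reversed 1. Those added left 128, moved 13 and reversed 1. For a list or gene, only a value at or beyond 1.5-fold counts as reversed, and a smaller one that changed sign counts as left or moved. Of other values the former left 3094, moved 449 and reversed 26, and the latter left 2105, moved 332 and reversed 18. Another 33 values, 8 of them thinned and 9 with a pseudocount of 5 UMIs, are left out because the pseudocount alone set their sign, as for genes at 0 UMIs in a class with far fewer UMIs. Minimums of 10 and 100 UMIs, the removal of ribosomal, mitochondrial and dissociation genes from correlations, and Scrublet's own calls, which removed 7 cells and so changed next to nothing, moved no value. The filter at 500 genes and 10% mitochondrial UMIs removed no spiny mouse cell, so it is void there. Where no reason is given, the cause was not tested.

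In cells thinned to 1000 UMIs the ERK inhibitor cell cycle in keratinocytes was at −0.98 (−1.11 without the pseudocount), ERK targets at −1.14 without it, differentiation at 0.13 with it, and the FGFR inhibitor cell cycle at −0.80 (−0.82). The values that follow reversed, with those without the pseudocount in brackets. Alternative activation in cluster 6 with the FGFR inhibitor was at −0.083 (−0.088). With the ERK inhibitor fibroblasts had fibrillar matrix at −0.070 without the pseudocount, Col1a1 at −0.93 (−1.0) and Postn at −0.86 (−1.05), and keratinocytes Dusp6 at 0.44 (0.13) and Acta2 at 1.69 (1.16), on 4 and 2 UMIs. With FGF2 and NRG1 keratinocytes had Lce1l at 0.10 (0.095), Col1a1 at −0.43 (−0.49), Mcm2 at −0.14 (−0.15) and Lor at 0.16 (0.16), cluster 6 Postn at −0.85 (−0.44), and chondrocytes fibrillar matrix at 0.018 without the pseudocount. Below the size set for a reversal, Tnc in mouse fibroblasts turned from −0.58 to 0.57 (0.80), and cytokines in mouse keratinocytes from 0.46 to −0.22 (−0.23). A thinned gene often rests on few UMIs.

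As a mean over cells, ERK inhibitor keratinocytes gave −1.19 for ERK targets, −0.77 for the cell cycle and 0.12 for differentiation, and mouse fibroblasts −0.76 for fibrillar matrix. Reversed were ERK inhibitor fibrillar matrix (−0.029) and Postn (−0.64) in fibroblasts and Acta2 (0.37) in keratinocytes, and mouse keratinocyte Lce1l (0.11), Lce1i (0.23) and Lor (0.10). With the control's mix of clusters the keratinocyte cell cycle was at −0.74, −0.20 and −0.16 with the ERK, ErbB2 and FGFR inhibitors and 0.018 with FGF2 and NRG1, and differentiation at 0.17 and 0.087 with the ErbB2 and FGFR inhibitors. The ERK inhibitor value covers 9 clusters with 231 of its 256 keratinocytes and 4517 of the 6852 of DMSO, against 14 clusters with all 6852 for the other inhibitors, so these are not comparable.

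Among cells whose own markers were highest, the keratinocyte cell cycle was at −1.04 with the ERK inhibitor and −0.87 with the FGFR inhibitor, and FGFR inhibitor fibrillar matrix at 0.23. Reversed were endothelial angiogenesis (−0.77) and fibroblast Serpina12 (−0.56) with the FGFR inhibitor, fibroblast Ube2c (0.66) with the ErbB2 inhibitor, and with FGF2 and NRG1 Lce1m (4.72), Lce1l (6.85) and Lce1i (6.93) in keratinocytes, Tchh (1.38), Sprr1a (3.73), Mgl2 (1.70) and Crct1 (1.0) in cluster 6 and Dcn (0.21) in chondrocytes. DMSO kept 8 cells of cluster 6, 24 of chondrocytes and 1 of endothelium there.

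With at least 300 UMIs the fibroblast Spearman correlations were −0.430 for the ERK inhibitor with FGF2 and NRG1, 0.553 for ERK with ErbB2 (covariance 0.395), 0.524 for ERK with FGFR (covariance 0.338) and 0.558 for ErbB2 with FGFR. Without genes at the free RNA level the keratinocyte Pearson correlation of the ERK inhibitor with FGF2 and NRG1 was −0.0542, and the mouse cell cycle in cluster 6 (−0.10) and limb patterning in ERK inhibitor keratinocytes (0.32) reversed. The whole annotated type gave −0.59 for mouse fibrillar matrix and reversed Dusp6 in mouse fibroblasts (−0.44) and haemoglobin in ErbB2 inhibitor keratinocytes (0.83). Without the deepest cell of each library ERK inhibitor fibrillar matrix was at 0.46, and Postn (−0.50) and Tnc (−3.91) in those fibroblasts and Serpina12 (−1.53) in FGFR inhibitor fibroblasts reversed. TMM gave −0.70 for the ErbB2 inhibitor cell cycle in keratinocytes. Removing the cells of highest doublet score gave 0.10 for FGFR inhibitor fibrillar matrix. Without immune cells, which only shrinks the denominator, chondrocytes with FGF2 and NRG1 made up 6.69% and the fibroblast cluster 4.13%.

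No paired analysis was possible because each group is 1 library and the groups share only the replicate number 1. Depth limits several classes, among them the 5 fibroblasts and 33 cells of cluster 6 of the ERK inhibitor library and the 32 PBS fibroblasts. Ratios of 2-fold can come from a few UMIs there. Cluster 7 held 106459 UMIs with the FGFR inhibitor and 122879 with the ErbB2 inhibitor, against 208802 in the PBS fibroblasts.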

Other observations

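Among the tests in this part, those of dilution by keratinocyte or chondrocyte RNA, an unusual DMSO library, the mix of fibroblasts or of cells within cluster 6, free RNA behind the interferon genes and changes member by member were chosen only after the result was seen. So were the removal of cells of highest doublet score, of the deepest cell and of genes at the free RNA level, the DMSO mix of clusters, the whole annotated type, and the genes named in endothelium and chondrocytes. In endothelium 17 of 21 cell cycle genes were lower and 1 higher with the ERK inhibitor (median −2.02, −2.40 to −1.26, −1.62 with 6 members at 0 set to their bound, and −0.82 after thinning). They were lower in 16 and higher in 0 of 21 with the ErbB2 inhibitor (−0.78, −1.30 to −0.65), and 16 and 0 of 21 with the FGFR inhibitor (−0.83, −1.45 to −0.59). Mki67 was at −1.66 (−2.47 to −1.05) and Ube2c at −1.80 (−2.73 to −1.13) with the ErbB2 inhibitor, and Cenpf at −2.47 (−3.68 to −1.69) with the FGFR inhibitor. With FGF2 and NRG1 12 of 24 were higher and 2 lower (0.60, 0.14 to 1.0, and 0.34 without 8 members at the free RNA level). Interferon genes were higher in 7 and lower in 0 of 10 with the ERK inhibitor (1.46, 0.15 to 2.07), with Gbp2 at 2.73 (74 UMIs in DMSO cells, 2.08 to 3.30), Mx1 at 1.90 (1.01 to 2.61) and Irf1 at 1.85 (1.04 to 2.51). The counts were 6 and 0 of 18 with FGF2 and NRG1 (0.34, 0.15 to 0.72), with Ifi27l2a at 1.17 (0.79 to 1.63) and Isg15 at 0.72 (0.37 to 1.12). Interferon medians were 0.13 (1 and 0 of 10) and 0.44 (2 and 1 of 10) with the ErbB2 and FGFR inhibitors. Angiogenesis genes were higher in 8 and lower in 0 of 11 with the FGFR inhibitor (0.73, 0.50 to 1.1), although the median was −0.77 among cells whose own markers were highest, of which DMSO had 1. Of the same list 8 were higher and 2 lower of 11 with the ERK inhibitor (0.88, −0.71 to 1.40), and the median was 0.08 (2 and 1 of 11) with the ErbB2 inhibitor. They were lower in 7 and higher in 0 of 14 with FGF2 and NRG1 (−0.47, −0.98 to 0.05), where Apln, the gene of a peptide made by sprouting vessel tips, was at −1.47 (−1.69 to −1.25, but −0.43 after thinning) and Cxcr4 at −0.99. Keratinocyte markers made up 3.18% of endothelial UMIs with DMSO, 0.170%, 2.98% and 1.15% with the ERK, ErbB2 and FGFR inhibitors, 0.332% with PBS and 0.218% with FGF2 and NRG1. Endothelial markers outnumbered those of each other type in 1 of the 977 DMSO cells. With the inhibitors, in the same order, they did so in 18 of 44, 7 of 431 and 21 of 240 cells. The spiny mouse cell cycle, interferon and angiogenesis values thus compare the annotated type, and how much other cells' RNA adds to them was not tested.

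Mouse chondrocytes (248 cells with FGF2 and NRG1 against 36 with PBS) had 14 of 17 hypoxia and glycolysis genes higher and 2 lower (1.11, 0.84 to 1.68, and 1.02 with 2 members at 0 set to their bound), with Pgk1 at 1.94 (1.43 to 2.63) and Ldha at 1.34 (1.08 to 1.63). Chondrogenic genes were higher in 9 and lower in 0 of 16 (0.68, 0.32 to 1.17), including Hapln1 (2.45, 2.14 to 2.81), Col2a1 (1.61, 1.5 to 1.73) and Acan (1.60, 1.44 to 1.78, and 0.83 after thinning), which encode the link protein, collagen and proteoglycan of cartilage. Among the 248 cells with FGF2 and NRG1, chondrocyte markers outnumbered those of each other type in 194, and among the 36 PBS cells in 14. How far these values reflect purer chondrocytes was not tested. Fibrillar matrix genes had 15 lower and 8 higher of 27 (−0.67, −0.97 to 0.71), with Thbs1 at −3.40 (−3.80 to −3.02, and −2.34 after thinning), Dcn at −1.95 (−2.06 to −1.84, but 0.21 among cells whose own markers were highest), Col1a1 at −1.46 (−1.67 to −1.25) and the collagen chaperone gene Serpinh1 at 1.14. That fibrillar median was 0.018 with thinned cells and no pseudocount. Cell cycle genes had 5 higher and 2 lower of 21 (−0.01). In spiny mouse chondrocytes they were lower in 14 and higher in 0 of 17 with the ErbB2 inhibitor (136 cells against 298, −1.20, −2.28 to −0.79), with Ccnb2 at 3 UMIs against 79 (−3.15, −5.85 to −1.94). They were lower in 17 and higher in 0 of 18 with the FGFR inhibitor (85 cells, −1.87, −2.65 to −1.19), with Top2a at 4 UMIs against 93 (−2.67). After thinning these medians were −1.15 and −0.87 with 3 members left in each. Chondrocyte markers outnumbered those of each other type in 24 of the 298 DMSO cells, 23 of the 136 and 10 of the 85, too few for a cell cycle median among them, so the annotated type is what is compared. Keratinocyte markers made up 3.23% of chondrocyte UMIs with DMSO, 2.20% and 1.12% with these inhibitors, 0.710% with PBS and 0.111% with FGF2 and NRG1.

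The cell cycle list was lower in keratinocytes with all 3 inhibitors. A difference in depth per cell is argued against, since the highest of the 3 medians was −0.80 (−0.96 to −0.67) with cells thinned to 1000 UMIs. Without the cells of highest doublet score the highest median was −0.58 (−0.71 to −0.36). Doublets in the DMSO library cannot be excluded by this, since doublet scoring did not work here. Because there was 1 DMSO library, an effect of the inhibitors cannot be told apart from an unusual DMSO library. With clusters weighted as in the DMSO library the medians were −0.20 and −0.16 for the ErbB2 and FGFR inhibitors, over 14 clusters with all 6852 DMSO keratinocytes, so much of these differences may lie in how many cells fall in each cluster. The ERK inhibitor value of −0.74 is not comparable, as it covers 9 clusters with 4517 of those cells. The share of keratinocytes in cycling clusters, which the same genes define, was 19.6% with DMSO and 12.9%, 12.3% and 13.5% with the inhibitors, and an effect of the inhibitors on it remains a hypothesis that needs further libraries.

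The fibrillar matrix list was lower in mouse fibroblasts with FGF2 and NRG1. Dilution by keratinocyte RNA is argued against, since keratinocyte markers made up 0.169% of their UMIs, below the PBS share, and dilution by chondrocyte RNA because chondrocyte markers stood at 3.15% of their level in the chondrocytes of that library. The highest median among thinned cells, cells without the deepest and the mean over cells was −0.76 (−1.35 to −0.51). Thinning changed the members by a median of 0.64 (0.41 to 0.75), where 0.64 would bring the list to 1.5-fold. Removing only the deepest cell of each library changed them by −0.007 (−0.087 to 0.10), with the list at −1.30. Given the values after thinning, a part played by deep cells or depth cannot be told apart from a change in expression. The same holds for another mix of fibroblasts among the 32 PBS cells, since those cells are few. The median of −0.59 over both clusters annotated as fibroblasts cannot decide this. It adds cluster 34, which Schwann cell markers lead, with 48 PBS cells and 66 cells with FGF2 and NRG1. A lower scar matrix programme with added growth factors may also explain the values and stays a hypothesis.

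In the mouse, interferon genes were higher in cluster 6 with FGF2 and NRG1. Free RNA of the library cannot be ruled out by keratinocytes, where the same list had a median of −0.084 (−0.62 to 0.29). With FGF2 and NRG1 they held a median of 9035 UMIs per cell against 4292.5 in cluster 6, so free RNA would weigh less in them. In endothelium, as given above, the list's median and its interval lay above 0. Depth per cell is argued against as the cause, because with cells thinned to 1000 UMIs the cluster 6 median was 1.55 (0.42 to 2.05, 12 of 16 members higher and 0 lower) and the members changed by a median of 0.021 (−0.39 to 0.40), where reaching 1.5-fold needed a change of −0.81. Another mix of cells among the 107 PBS cells of cluster 6 cannot be told apart either, since those cells are few and come from 1 library. A response of these cells to the growth factors may be the reason and was not tested.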
